A study of Rhinichthys cataractae with 82 samples.

How the data were processed

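Liver RNA was sequenced from 82 individual longnose dace (Rhinichthys cataractae), a small river fish. Per the labels, wild fish were caught in the Bow River, and some were sampled before caging (day 0). The others were caged in raceways that received river water (controls) or river water with 5% final effluent of a wastewater treatment plant, and were sampled after 7, 14 or 28 days. Libraries were poly(A)-selected and strand-specific and were sequenced on an Illumina NovaSeq, per the labels. Each fish gave 1 library.

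The authors trimmed reads with fastp and quantified them with RSEM against a transcriptome assembled without a genome. Tool versions and the alignment program are not given in the sources used here. The authors deposited 1 table of 222746 transcript clusters with annotation. Per the file headers it holds an estimated read count for each library, the RSEM expected count, and 96.32% of these values are whole numbers to within 1e-9. It also holds an FPKM value per library, deposited by the authors, which was not used here. The deposited table further gives, for 8 comparisons that pool the sexes, a log2 fold change and a q-value computed by the authors, of which only the counts of clusters passing are described in the closing section. Genome positions were not used here, and genes are identified by name alone. Totals of estimated counts per library in units of 1e6 ran from 14.25 to 22.36 (median 15.6). No pair of libraries within a group was a duplicate: over 201 pairs, the lowest chi-square per degree of freedom between libraries was 71.92, on clusters with a mean count of at least 50.

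Each cluster took the gene symbol of its best Swiss-Prot match in the deposited annotation (42687 clusters) or, where that entry has no symbol, its protein name (2250 clusters). Clusters without either were left out of the tests, and named clusters held 80.81% to 86.74% of the counts of a library. Counts were summed per name and rounded, which gave 17465 names, of which 9617 combine more than 1 cluster. A name can therefore join gene copies that share reads, and changes in 1 copy are not separated. Names are those of Swiss-Prot entries from any organism, so that mimi_r871 and ddb_g0292642 carry viral and slime mould entry names. Fish are named by a letter for the sex and the number in their label (M259, F317). Names were kept with edgeR's filterByExpr over the 14 groups (minimum count 10, minimum total 15), which left 13840.

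Tests used edgeR 4.0.16 in R 4.3.3 with TMM normalisation and a quasi-likelihood F test. The model had 1 mean for each of the 14 combinations of day, water and sex, with 68 residual degrees of freedom and a common dispersion of 0.295 (a coefficient of variation of 54.3% between fish). There were 17 comparisons. Differences between waters, and between caged controls and day 0, were averaged over the sexes unless a sex is named, and the difference between sexes in caged controls was averaged over the 3 days. P-values were adjusted with the Benjamini-Hochberg method over all names tested, and a name was called at an adjusted p below 0.05. Changes are log2 ratios with standard errors (SE), and levels are counts scaled to 1e6 per library (CPM) with the standard deviation (SD) between fish. The p-values measure the spread among fish. The labels do not tie a fish to its raceway or cage, so effects of single raceways could not be modelled.

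Before the data were examined, 43 gene lists were fixed, 30 of functions and 13 of cell type markers. Protein names standing for list members, and names to exclude from lists, were added after the table was seen and before any list was tested. Lists were tested with camera in limma 3.58.1 (preset correlation 0.01, on log2 CPM with a prior count of 2), with adjustment over lists. Camera with an estimated correlation and fry were run beside it. The rule for named genes was also fixed beforehand. It takes, among called names with a mean of at least 1 CPM, the 8 largest rises and 8 largest falls shared by at least 9 of 12 fish (5 of 6 within 1 sex), the 4 members with the smallest p of each list that was called or has at least 3 called members, and a fixed set of indicator genes. Results for some genes are not reported here. Genes named outside this rule are said to be chosen after their values were seen.

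Alternatives fixed before the data were examined were DESeq2 size factors, no filter on low counts, DESeq2 1.42.0, limma-voom with quality weights, a fit of the compared groups alone, each cluster tested on its own (56262 clusters), covariates for exocrine pancreas and red blood cell lists, sex as an additive term, and leaving out each fish in turn. After seeing the data, 3 more were added. The first leaves out 13 libraries, 12 whose mean log2 CPM of the oocyte genes gdf9, bmp15, zar1 and zp2 is above 2 and 1 whose hepatocyte list mean is below 8. The second adds the means of the gonad, intestine and muscle lists as covariates. The third leaves out 3962 clusters whose nucleotide match in the deposited annotation is a rat or mouse sequence. A name below the filter on low counts in an alternative, or without clusters left, is not tested there and is counted apart from the alternatives with a value. Group labels were also permuted, within day and sex for water (70 splits), within sex for caging (100 splits) and within day and water for the sexes (100 splits), each set including the observed grouping. The procedure was tested on simulated data with the same library sizes. For the mean effluent comparison, 83.1% of changes of 1 on the log2 scale and 97% of changes of 2 were recovered. Of its calls, 11.6% were false, above the share of 0.05 aimed at. For the caged controls at day 28 these values were 56.1%, 84.8% and 6.3%. Simulated names varied independently of each other around 1 mean profile. The rates therefore do not cover names that move together, such as those of other tissues in these libraries. Figures were drawn with matplotlib 3.10.9. Estimated counts limit the precision of weakly expressed names, and fish-to-fish spread limits the rest.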

Results

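Liver expression was measured in 82 longnose dace, each with 1 library. Wild fish sampled at day 0 numbered 6 males and 4 females. At days 7, 14 and 28, caged fish from river water and from 5% effluent numbered 6 males and 6 females per water and day. Library totals, in units of 1e6 estimated reads, ran from 14.25 to 22.36 with a median of 15.6, and the highest stood apart from the next, 17.97. In all, 13840 gene names were tested in each comparison.

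The first question was whether treated wastewater changed the liver transcriptome against river water. Averaged over the 3 days and both sexes, transcripts of red blood cells fell in effluent fish. The gene slc4a1, the anion exchanger of the red cell membrane, fell by 1.11 on the log2 scale (SE 0.20, adjusted p = 0.00909), from 10.4 ± 8.45 CPM (SD, n = 36) to 4.80 ± 3.05 CPM (n = 36), and 33 of 36 effluent fish lay at or below the control median. The globin hba fell from 51.5 ± 42.7 to 24.8 ± 19.6 CPM (log2 change -1.08, SE 0.23, adjusted p = 0.0208), with 28 of 36 effluent fish at or below the control median. The globins hbb2, hbaa1 and ba2 fell as well, with changes of -1.14, -1.12 and -0.93 (SE 0.23, 0.23 and 0.21). These falls were shared by 30, 30 and 31 of 36 fish. Of 81 alternatives, 72 leave out 1 fish each. Of the 81, 3, 8, 5 and 7 ended the calls of slc4a1, hba, hbb2 and hbaa1. None of the 3 that ended the call of slc4a1 was the loss of a single fish. The call of ba2 ended in 49, and its change ran from -1.0 to 0.06. Changes of the other 3 globins came to between -0.02 and 0.00 with the pancreas and red blood cell covariates.

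Of the 15 members of the red blood cell list, 4 fell over all genes and 11 fell when adjusted over the list alone, and none rose. The list median was -0.69 (camera adjusted p = 7.45e-21), and the call held with an estimated correlation (adjusted p = 0.00433) and with fry (adjusted p = 0.00242). At days 7, 14 and 28 the list medians were -0.55, -0.46 and -0.66. Each single day had a camera call that was lost with an estimated correlation (adjusted p = 0.642, 0.558 and 0.697). In all, 8 names were called in this comparison, 7 lower and 1 higher. The diacylglycerol kinase dgkb fell by 1.25 (SE 0.26, adjusted p = 0.0207), in 30 of 36 fish. The remaining calls were outside the naming rule and were chosen after their values were seen. The gene caln1 fell by 1.95 (SE 0.43, adjusted p = 0.0396; 25 of 36 fish) and npy1r, a neuropeptide Y receptor, rose by 2.13 (SE 0.45, adjusted p = 0.0208; 28 of 36 fish). Their calls were lost in 35 and 9 of 81 alternatives. The number of calls went to 0 with limma-voom and with the pancreas and red blood cell covariates. It was also 0 without the 13 libraries with oocyte or little liver RNA, an alternative added after seeing the data, where slc4a1 had a change of -1.11 with an adjusted p of 0.0518. It went to 1 without day 28 control female F317 or control male M308, and to 5 without any of day 7 effluent male M180, day 14 control female F187, control male M245, effluent male M259 or effluent female F272.

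**Figure D1:**
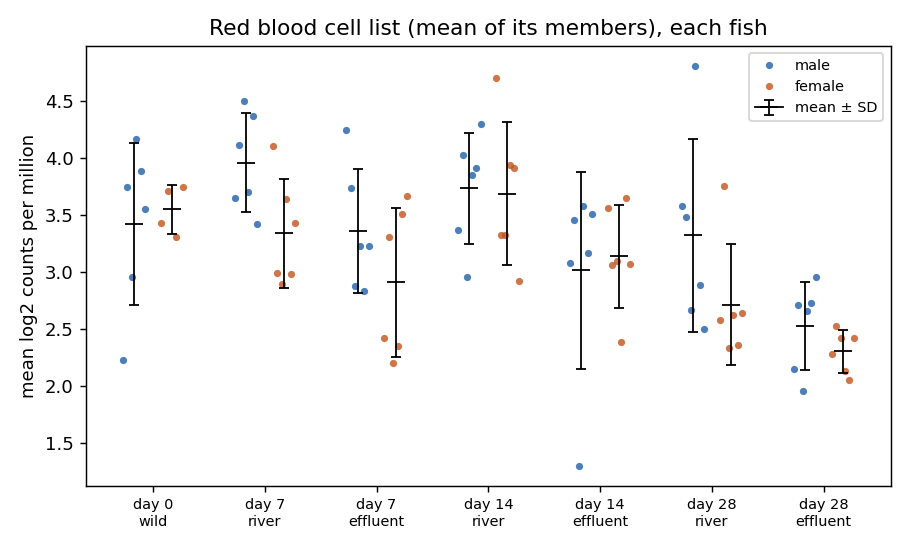
Mean log2 CPM of the 15 members of the red blood cell list in each fish (points), by day, water and sex, with the group mean and SD (black). Day 28 control female F317 has the value 3.76 and day 14 effluent male M259 the value 1.30.

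None of the fixed indicators of effluent exposure was called in this average. The yolk precursor vtg1, a marker of estrogen exposure in male fish, had a log2 change of -0.63 (SE 0.46, adjusted p = 0.822), and the estrogen receptor esr1 had 0.05 (SE 0.20, adjusted p = 0.994). In males, vtg1 was at 33.1 ± 32.0 CPM in effluent against 82.9 ± 63.5 CPM in river water at day 7, at 22.8 ± 21.1 against 138 ± 267 CPM at day 14 and at 18.8 ± 19.1 against 39.9 ± 52.7 CPM at day 28 (n = 6 each), with log2 changes of -1.33, -2.60 and -1.09 (SE 1.13, 1.18 and 1.13). Among control males at day 14, M207 had 682 CPM (9.41 in log2 CPM), where the next highest had 5.53 log2 CPM. In females vtg1 was at 2420 ± 5280 against 488 ± 494 CPM at day 7 (log2 change 2.31, SE 1.16), with the highest effluent female at 13200 CPM. It was at 519 ± 739 against 852 ± 1380 CPM at day 14 and at 579 ± 640 against 737 ± 840 CPM at day 28. None of these was called. The changes were -0.10 (SE 0.14) for cyp1a1, induced by planar aromatic compounds through the aryl hydrocarbon receptor, and 0.04 (SE 0.17) for the drug-metabolising cytochrome cyp3a27. They were -0.41 (SE 0.27) for the stress chaperone hsp70, -1.62 (SE 0.70) for Metallothionein-like protein type 3, 0.11 (SE 0.11) for the growth factor igf1 and -0.13 (SE 0.15) for the gluconeogenic enzyme pck1. Their adjusted p-values ran from 0.604 to 0.999. The metallothionein was at 2.47 CPM or less in every group, its change ran from -2.30 to -0.51 over the alternatives, and at day 14 effluent females had 2.47 ± 4.92 CPM (n = 6) against 0.695 ± 0.807 CPM (n = 6), so its value is unstable.

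At day 7, effluent fish had 45 called names, 39 higher and 6 lower. Of the 39 higher names, 26 take most of their reads from clusters whose nucleotide match in the deposited annotation is a rat or mouse sequence. One example is gpx3, a secreted glutathione peroxidase, at 5.59 ± 3.83 against 0.794 ± 0.420 CPM (log2 change 2.82, SE 0.54, adjusted p = 0.00421; 10 of 12 fish above the control median). Others are the sodium pump subunit atp1b1 (2.53, SE 0.49; 11 of 12 fish) and the amino acid transporter slc7a13 (2.72, SE 0.62; 11 of 12 fish). The kidney genes kap, umod and cdh16, chosen after their values were seen, rose by 2.39, 1.69 and 2.77 (SE 0.56, 0.42 and 0.66). In the list of conjugating enzymes and transporters, 4 of 42 members rose (5 when adjusted over the list alone; camera adjusted p = 0.686). All 4 are names with a rat or mouse match, among them sult1c2a (2.31, SE 0.55) and slco1a3 (2.78, SE 0.66). The mean over all 70 tested names of this kind was 1.05 ± 0.56 log2 CPM (SD, n = 6) in effluent males against -0.03 ± 0.28 (n = 6) in control males, and 0.67 ± 0.93 (n = 6) against -0.24 ± 0.36 (n = 6) in females. The calls of kap, umod and cdh16 were lost in 14 of 33, 24 of 34 and 13 of 28 alternatives, and those of slc7a13, sult1c2a and slco1a3 in 8, 14 and 15 of 33. In 6 further alternatives cdh16 was not tested. The change of umod was 1.29 without effluent female F164 and 0.33 without the clusters matching rat or mouse. Without these clusters, 11 names were called at day 7, all among the 45.

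Among names of the fish, 4 falls at day 7 met the naming rule. The angiopoietin-like angptl7 fell from 23.0 ± 8.93 to 14.3 ± 4.12 CPM (log2 change -0.65, SE 0.14, adjusted p = 0.0166), in 12 of 12 fish. The transcription factor crebzf fell by 0.57 (SE 0.13; 11 of 12 fish). Also lower were the kinase sgk1-a, which regulates ion transport (-0.74, SE 0.18; 12 of 12), and add2, a protein of the membrane skeleton (-1.51, SE 0.36; 12 of 12). Their calls were lost in 22 and 15 of 34 alternatives, with changes from -0.82 to -0.65 and from -1.64 to -1.17, and those of angptl7 and crebzf in 5 of 34 each. An MHC class I name (RT1 class I histocompatibility antigen, AA alpha chain) rose by 5.01 (SE 1.20, adjusted p = 0.0316), in 9 of 12 fish. Its call was lost in 21 of 34 alternatives, with changes from 1.53 to 6.89, and the change was 2.90 without effluent male M169 (adjusted p = 0.322). In the muscle list 2 of 23 members rose (6 when adjusted over the list alone), among them Parvalbumin beta (7.69, SE 1.40), which lay above the control median in 6 of 12 fish. Its change ran from 1.31 to 8.57 over 32 alternatives, 5 of which ended its call, and it was not tested in 2 more. It was 4.44 without effluent male M143 and 2.25 without effluent female F145. The camera call of this list was lost with an estimated correlation (adjusted p = 0.754). No member of the cell cycle list (median 1.41), the intestine list (median 1.64) or the gonad list (median 1.0) was called over all genes. When adjusted over the list alone, 19, 6 and 0 members were higher (adjusted p = 0.754 for each list with an estimated correlation). The mean of the 4 oocyte genes was 6.20, 4.38, 6.94 and 6.17 log2 CPM in effluent fish F145, F152, F158 and M180. It was 5.87, 5.99 and 2.93 in control females F74, F93 and F100. The intestine list mean was 6.79, 5.92 and 5.74 in effluent fish M143, M169 and F145, and at most 4.96 in controls (M110). Members of the ribosomal protein list had a median of -0.25 and those of the oxidative phosphorylation list of -0.20, with camera adjusted p = 9.88e-28 and 7.88e-14. Both calls were lost with an estimated correlation (adjusted p = 0.642 for each). The number of calls at day 7 went to 0 with limma-voom or with sex as an additive term and to 11 without the 13 libraries. It went to 22 without effluent male M143, to 26 or 27 without control males M110 or M71, and to 27 without effluent female F179.

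At day 14, effluent fish had 390 called names, 174 of them higher. The macrophage receptor mrc1 rose from 25.8 ± 11.9 to 107 ± 218 CPM (log2 change 1.69, SE 0.40, adjusted p = 0.0173; 11 of 12 fish). With it, 2 of the 10 members of the macrophage list rose, the other being the lysosomal protease lgmn (0.60, SE 0.18). In the granulocyte list 2 of 12 members rose, the peroxidase mpo (3.02, SE 0.69; 7 of 12 fish) and the oxidase subunit cybb (0.95, SE 0.28; 8 of 12 fish). In the antigen presentation list 3 of 16 members rose, b2m by 0.86, cd74 by 0.97 and hla-dpa1 by 1.40, and 1 fell, h2-d1, a name with a rat or mouse match. The intestinal peptide transporter slc15a1 rose by 1.98 (SE 0.51; 7 of 12 fish) and the peptidase anpep by 1.63 (SE 0.45; 9 of 12 fish). In all, 2 of 11 members of the intestine list rose (8 when adjusted over the list alone). The macrophage, granulocyte and antigen presentation lists lost their camera calls with an estimated correlation (adjusted p = 0.558 for each), as did the intestine list (adjusted p = 0.605). Every rise named in this paragraph lost its call without effluent male M259, without the 13 libraries and with limma-voom. Without M259 the changes were 0.80 for mrc1 (adjusted p = 0.289), 0.32 for lgmn, 2.68 for mpo, 0.70 for cybb, 0.57 for b2m, 0.64 for cd74, 1.06 for hla-dpa1, 1.67 for slc15a1 and 1.01 for anpep (adjusted p = 0.267). Without effluent female F256, mpo, slc15a1 and anpep went to 1.39, 1.26 and 1.11 (adjusted p = 0.264, 0.188 and 0.205). The calls of lgmn, cybb, b2m, cd74 and hla-dpa1 were also lost without various other single fish.

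Germ cell transcripts moved the other way at day 14. In the gonad list 10 of 24 members fell (14 when adjusted over the list alone), among them the oocyte growth factor gdf9 (-6.57, SE 1.48; 11 of 12 fish), the egg factor zar1 (-5.19, SE 1.29; 11 of 12 fish) and the germ cell helicase ddx4 (-4.68, SE 1.17; 12 of 12 fish). The list lost its camera call with an estimated correlation (adjusted p = 0.816). In the cell cycle list 8 of 45 members fell (24 when adjusted over the list alone; adjusted p = 0.973 with an estimated correlation), among them ccnb1 (-4.30, SE 1.05). Without control female F227, gdf9, zar1, ddx4 and ccnb1 had changes of -5.46, -3.48, -3.56 and -2.72 (adjusted p = 0.0617, 0.209, 0.124 and 0.216), and their calls were also lost without control male M209. Without the 13 libraries zar1, ddx4 and ccnb1 had changes of -0.82, -1.39 and 0.00, and gdf9 was not tested. In the muscle list 7 of 23 members fell (12 when adjusted over the list alone; adjusted p = 0.619 with an estimated correlation). The red cell gene slc4a1 fell by 1.39 (SE 0.35, adjusted p = 0.0204), in 12 of 12 fish, and lost its call without control male M245 (-1.06) or effluent male M259 (-1.37). The 4 oocyte genes gdf9, bmp15, zar1 and zp2 had a mean of 6.74 and 5.00 log2 CPM in the day 14 control males M209 and M223 and 3.88 in control female F227. Effluent male M259 had an intestine list mean of 7.37 and a hepatocyte list mean of 6.12, where the next lowest male of its group had 10.1. Names with a rat or mouse match made up 23 of the lower names, with a median of -1.49 over all 70. The number of calls went to 0 without the 13 libraries, with the gonad, intestine and muscle covariates (both added after seeing the data) and with limma-voom. It went to 47 without effluent male M259, to 51 without control male M209, to 114 without control female F227 and to 139 without effluent female F256. With the pancreas and red blood cell covariates 84 names were called, 5 of them higher.

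**Figure D2:**
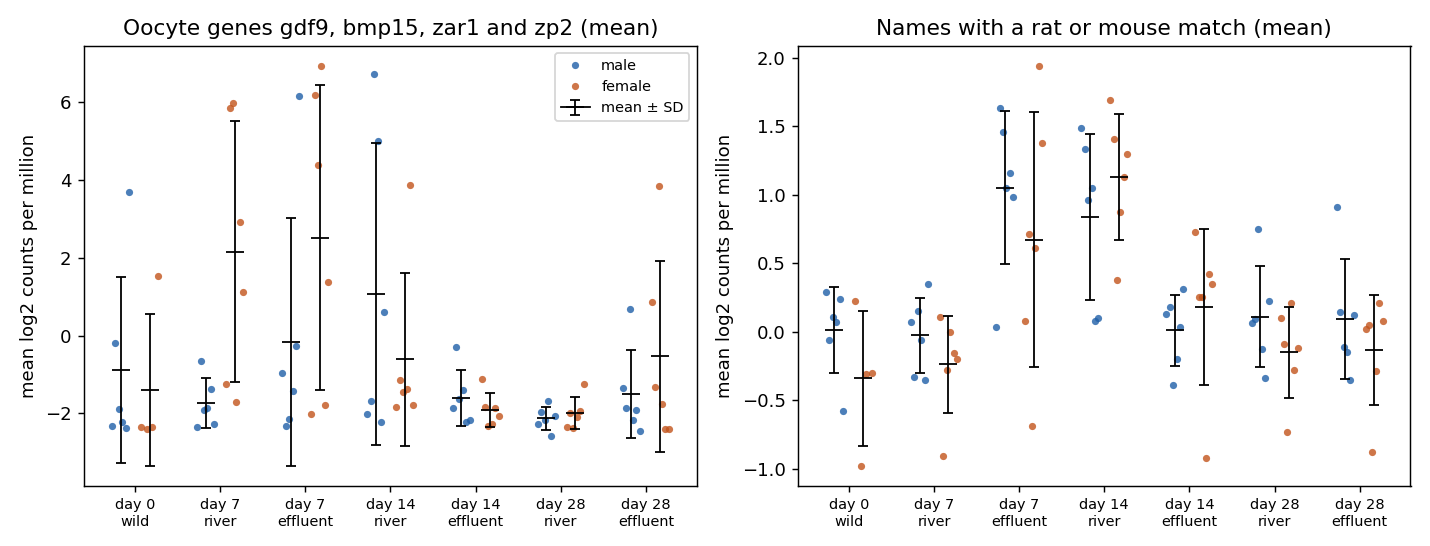
Mean log2 CPM in each fish (points) of 4 oocyte genes (left) and of the 70 tested names with a rat or mouse match (right), by day, water and sex, with the group mean and SD (black). Oocyte means reach 6.74 in males and 6.94 in females, and the rat and mouse mean in males is 1.05 ± 0.56 in effluent at day 7 and 0.84 ± 0.61 in river water at day 14.

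At day 28, 3 names were called, all outside the naming rule and chosen after their values were seen. The cardiac myosin light chain myl7 rose by 7.65 (SE 1.26, adjusted p = 0.00115; 7 of 12 fish) and myoglobin, mb, by 3.65 (SE 0.75, adjusted p = 0.0325; 6 of 12 fish), while mimi_r871 fell by 5.79 (SE 1.16, adjusted p = 0.0325; 8 of 12 fish). Effluent fish had 4.29 ± 10.1 CPM of myl7 (n = 12) against 0.00565 ± 0.0196 CPM in controls (n = 12). They had 17.9 ± 39.8 CPM of mb against 1.17 ± 0.664 CPM. For both genes the SD among effluent fish exceeded their mean, so the rises were not shared by the group. The change of myl7 ran from 2.62 to 15.44 over the 28 alternatives with a value, 1 of which ended its call. In 6 more myl7 was below the filter on low counts and so not called, among them those without any of M375, F367, F395 and F397, so 7 of 34 had no call. The change of mimi_r871 ran from -6.38 to -1.88, with its call lost in 14 of 32 alternatives and no test in 2 more. That of mb was lost in 18 of 34, with changes from 0.64 to 4.03, and with 2.19 without effluent male M375 and 2.59 without effluent female F395. The heart hormone gene nppa, chosen after its values were seen, was at 7.76 ± 11.8 CPM (n = 6) in effluent females, at 2.04 ± 4.99 CPM (n = 6) in effluent males and at 0 in all controls of that day. The list of the unfolded protein response had a median of 0.35 (camera adjusted p = 3.69e-05) and the cholesterol synthesis list of 0.57 (camera adjusted p = 8.15e-05), with no member called and adjusted p = 0.747 for each with an estimated correlation. The chaperone hsp70 had a log2 change of -1.50 (SE 0.46, adjusted p = 0.347). The count went to 0 without any of effluent male M375 or effluent females F367, F395 and F397, to 1 without control male M329, and to 5 or 6 without control male M321, control female F323 or effluent males M365 and M384. It was 53 with DESeq2 and 0 with limma-voom.

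Within each sex, the effluent comparison asks whether males or females respond on a given day. In males, 1 name was called at day 7, angptl7, which fell from 28.4 ± 8.92 to 13.5 ± 5.02 CPM (log2 change -1.07, SE 0.20, adjusted p = 0.0198; 6 of 6 fish). Its call was lost without control male M110 (-0.91) and without effluent males M167, M169 or M180 (-1.07, -0.94 and -1.03). The count at day 7 went to 0 without any of these 3 effluent males, to 22 without effluent male M132, and to between 2 and 7 without any of control males M71, M94, M104, M110 and M117 or effluent males M143 and M156. It was 291 with DESeq2 and 2 with limma-voom. At day 14, 590 names were called in males, 318 of them higher. The egg envelope gene zp2 was at 0.701 ± 0.752 CPM in effluent against 230 ± 451 CPM in controls (log2 change -8.37, SE 2.21, adjusted p = 0.0279; 6 of 6 fish). Control males M209 and M223 had 1130 and 237 CPM of zp2 and the other control males 0.071 to 9.64 CPM, and the change was -6.08 without M209 (adjusted p = 0.125), -8.06 without effluent male M259 (adjusted p = 0.144) and -1.60 without the 13 libraries. The count of 590 went to 1 without effluent male M259, to 76 and 212 without control males M209 and M223, and to 393 and 296 without effluent males M252 and M270. It was 2 without the 13 libraries. At day 28 edgeR called 0 names in males, with 803 at an unadjusted p below 0.05, where DESeq2 called 29 and limma-voom 0.

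In females, the muscle list fell at day 14, with 9 of 23 members lower (19 when adjusted over the list alone). Its median was -4.72, and its camera call held with an estimated correlation (adjusted p = 0.00261) and with fry (adjusted p = 0.0174). Creatine kinase, ckm, fell from 98.5 ± 107 to 2.37 ± 0.909 CPM (log2 change -5.37, SE 0.99, adjusted p = 0.0055; 6 of 6 fish). The calcium pump atp2a1 (-4.54, SE 0.84), Troponin C, skeletal muscle (-4.99, SE 1.01) and Parvalbumin beta (-9.49, SE 1.97) fell too. Members of this list made up 9 of the 14 calls, of which 1 was higher and 13 lower. The mean of the muscle list was 4.04, 4.36 and 5.11 log2 CPM in control females F187, F211 and F229 and at most 0.89 in the other females of that day. The count went to 7 without control female F187, to 4 without control female F229, and to between 2 and 7 without any of effluent females F254, F269, F272, F286 and F289. It was 2 with the gonad, intestine and muscle covariates, where Parvalbumin beta turned to 4.92 and ckm, atp2a1 and Troponin C, skeletal muscle went to -0.22, -0.26 and -0.31; the muscle covariate is built from these genes. At day 7, 2 names rose in females, the immunoglobulin name igkv1d-12 (8.60, SE 1.56, adjusted p = 0.00767; 5 of 6 fish) and napsa (adjusted p = 0.0216), a name with a rat or mouse match that was at 0 in all 6 controls and was chosen after its values were seen. Their calls were lost in 7 of 20 and 8 of 19 alternatives, with 1 and 2 more in which they were not tested. The change of igkv1d-12 ran from 1.76, without effluent female F164, to 10.06. Without control females F74, F96 or F100 or effluent female F164, 0 were called. At day 28 edgeR called 0 names in females, with 756 at an unadjusted p below 0.05, where DESeq2 called 51 and limma-voom 1.

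The difference of the effluent effect between sexes was itself tested, and 1 name passed, ddb_g0292642 (difference 9.84, SE 1.89, adjusted p = 0.0484), chosen after its values were seen. The count was 0 without the filter on low counts, with limma-voom, in a fit of the compared groups alone, with each cluster tested on its own, without the 13 libraries and with the gonad, intestine and muscle covariates. Leaving out single fish gave 0 to 5 calls and moved the count in 50 of 72 fits. DESeq2 called 13 names, with 0 shared. Between days 28 and 7 the difference of the effluent effect passed for 4 names. The mono-ADP-ribosyltransferase art3 had a difference of -2.26 (SE 0.41, adjusted p = 0.00774), from 1.64 at day 7 to -0.62 at day 28. The muscle genes mb and myl7 had differences of 4.69 (SE 1.01) and 9.26 (SE 1.71), and napsa of -4.33 (SE 0.92), with myl7 and napsa chosen after their values were seen. The count was 0 without the 13 libraries and 1 with limma-voom or in a fit of the compared groups alone. Leaving out single fish gave 1 to 7 calls and moved the count in 26 of 48 fits. Over the alternatives the difference ran from 0.03 to 4.94 for mb and from -4.49 to -1.77 for napsa, with their calls lost in 38 of 57 and 38 of 54 alternatives, and napsa not tested in 3 more. That of art3 ran from -2.53 to -1.94, with its call lost in 1 of 57, and that of myl7 from 3.02 to 17.39, with its call lost in 4 of 52 and no test in 5 more.

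The next question was how fish in the river-water cages differed from wild fish at day 0. Cholesterol synthesis fell at every time. At day 7, 305 names were called, 121 higher and 184 lower. Among them, 24 of the 27 members of the cholesterol synthesis list fell, also when adjusted over the list alone (median -2.67, camera adjusted p = 5.42e-59; adjusted p = 8.86e-06 with an estimated correlation). The gene cyp51, a sterol demethylase, went from 114 ± 86.0 CPM (SD, n = 10) to 8.22 ± 6.57 CPM (n = 12), a log2 change of -3.91 (SE 0.53, adjusted p = 2.25e-07), with 12 of 12 caged fish below the day 0 median. Other enzymes of the pathway fell alike, among them hmgcs1 (-3.03), idi1 (-3.34), fdft1 (-3.06), msmo1 (-4.29) and mvd (-3.90), each in 12 of 12 fish.

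Smaller groups moved at day 7 as well. In the fatty acid synthesis list 3 of 24 members fell (6 when adjusted over the list alone): acly (-1.56), acss2 (-1.5) and elovl6 (-2.26). The camera call of this list was lost with an estimated correlation (adjusted p = 0.46). In the stellate cell and fibroblast list 6 of 30 members fell (11 when adjusted over the list alone), among them the collagen col1a1 (-1.55, SE 0.30) and the matrix protein sparc (-1.17, SE 0.24), with adjusted p = 0.0777 with an estimated correlation. Outside the lists, the immediate early gene fosb fell by 3.99 (SE 0.58) and the transcription factor tbx2b rose by 1.71 (SE 0.31), each in 12 of 12 fish. In the list of aryl hydrocarbon receptor targets 1 of 5 members rose (3 when adjusted over the list alone), with the camera call lost with an estimated correlation (adjusted p = 0.0777). There, cyp1a1 had a change of 0.85 (SE 0.25, adjusted p = 0.0549). The number of calls went to 185 without day 0 female F53 and to 198 without day 0 female F55, and to 819 with limma-voom.

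**Figure D3:**
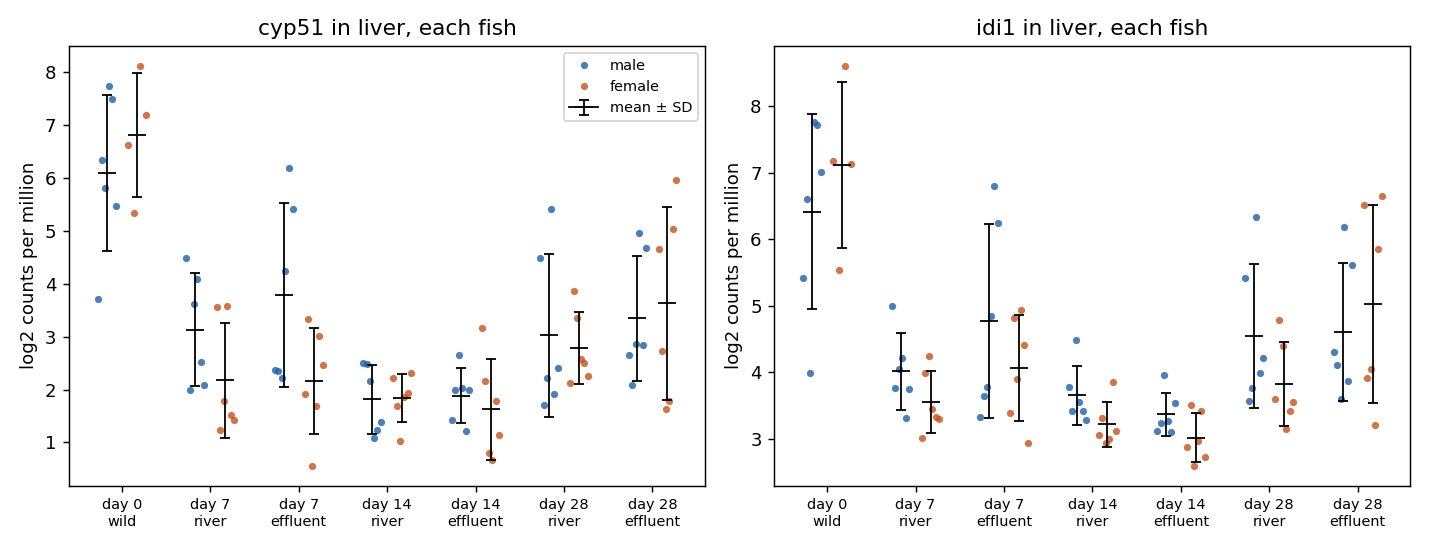
Log2 CPM of cyp51 (left) and idi1 (right) in each fish (points), by day, water and sex, with the group mean and SD (black). The wild day 0 fish have a mean cyp51 level of 114 CPM, and caged controls have 8.22 CPM at day 7 and 3.62 CPM at day 14.

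At day 14, 1137 names were called, 521 higher and 616 lower. Cholesterol synthesis remained low, with 24 of 27 members lower (median -3.02, camera adjusted p = 2.25e-53; adjusted p = 2.74e-05 with an estimated correlation). The level of cyp51 was 3.62 ± 1.32 CPM (log2 change -5.01, SE 0.55, adjusted p = 3.57e-10), and the low density lipoprotein receptor ldlr fell by 2.12 (SE 0.22). In the fatty acid synthesis list 7 of 24 members fell, among them fasn, the fatty acid synthase (-2.75, SE 0.67), with adjusted p = 0.724 with an estimated correlation. In the proteasome list 26 of 36 members fell (33 when adjusted over the list alone), among them psmd11b (-1.12, SE 0.21), psmd8 (-1.02, SE 0.22) and psmc5 (-0.69, SE 0.16), each in 12 of 12 fish. The camera call of this list was lost with an estimated correlation (adjusted p = 0.299), while fry gave adjusted p = 0.00106. In the glucocorticoid list 4 of 14 members fell (6 when adjusted over the list alone; adjusted p = 0.421 with an estimated correlation). The gene fkbp5, a feedback regulator of the glucocorticoid receptor, fell by 2.12 (SE 0.50), and the others were errfi1 (-1.09, SE 0.25), ddit4 (-1.84, SE 0.57) and tsc22d3 (-0.88, SE 0.28), the last with its call lost in 13 of 31 alternatives.

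In the heat shock list at day 14, 5 of 24 members fell and 1 rose (7 and 1 when adjusted over the list alone; adjusted p = 0.724 with an estimated correlation). There, hsp70 fell by 2.65 (SE 0.50), with hspd1 (-1.02, SE 0.30) and hspe1 (-1.04, SE 0.31). In the oxidative phosphorylation list 9 of 72 members fell and 1 rose (adjusted p = 0.724 with an estimated correlation), with ndufb2 at -0.83 (SE 0.15). In the stellate cell and fibroblast list 8 of 30 members fell (adjusted p = 0.431 with an estimated correlation). The pentose phosphate enzyme pgd fell by 1.80 (SE 0.36), as did the growth hormone receptor ghr (-0.88, SE 0.21) and the immediate early gene fosb (-4.78, SE 0.60). The rises included cyp7a1, the rate-limiting enzyme of bile acid synthesis, by 1.94 (SE 0.65; 9 of 12 fish), the clock gene cry2 by 1.58 (SE 0.33; 11 of 12 fish) and the DNA repair gene ddb2 by 1.25 (SE 0.22; 12 of 12 fish). The call of cyp7a1 was lost in 17 of 31 alternatives, and its change was 1.04 without control female F211 (adjusted p = 0.294). Of the names with a rat or mouse match, 37 rose and 1 fell, with a median of 2.22 over all 70. In all, 1086 names were called without the clusters matching rat or mouse. The count was 749 without day 0 female F53, and limma-voom called 2469.

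At day 28, 3488 names were called, 1770 higher and 1718 lower. Cholesterol synthesis was still lower, in 23 of 27 members (24 when adjusted over the list alone), with a median of -2.28 (camera adjusted p = 8.41e-22; adjusted p = 0.021 with an estimated correlation). The gene fdps, a prenyl transferase of the pathway, had 17 ± 11.4 CPM against 149 ± 81.1 CPM at day 0 (log2 change -3.16, SE 0.40, adjusted p = 3.68e-09). The pathway enzymes sc5d, mvk and pmvk fell as well, with changes of -3.01, -2.60 and -1.25. Heat shock genes had risen by this time. In that list 13 of 24 members were higher and 1 lower, the same numbers as when adjusted over the list alone, with a median of 0.70 (camera adjusted p = 1.3e-09; adjusted p = 0.021 with an estimated correlation). The inducible chaperone hsp70 rose by 3.23 (SE 0.55, adjusted p = 4.1e-06; 12 of 12 fish), and its cochaperone dnaja4 went from 6.16 ± 9.84 to 47.8 ± 28.2 CPM (log2 change 3.24, SE 0.51, adjusted p = 1.01e-06; 12 of 12 fish). The cochaperones dnajb1, bag3 and fkbp4 rose by 2.46, 1.71 and 1.60 (SE 0.32, 0.23 and 0.20), each in 12 of 12 fish.

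Fat oxidation genes fell at day 28, with 19 of 36 members lower and 1 higher (median -0.79, camera adjusted p = 7.07e-10; adjusted p = 0.246 with an estimated correlation). Carnitine palmitoyltransferase cpt2 (-1.78, SE 0.26), the thiolase acaa1 (-1.53, SE 0.24) and pdk4, a brake on pyruvate oxidation (-1.61, SE 0.27), fell in 12 of 12 fish each. In the ribosome biogenesis list 19 of 41 members rose (22 when adjusted over the list alone; adjusted p = 0.57 with an estimated correlation). Among them were nob1 (1.14, SE 0.13), the helicase ddx21 (1.20, SE 0.24) and the RNA polymerase I subunit polr1a (0.89, SE 0.14). In the oxidative phosphorylation list 21 of 72 members fell, ndufb2 (-1.23, SE 0.15) among them, and 1 rose, sdhb (0.59, SE 0.12), with adjusted p = 0.798 with an estimated correlation. The clock list went both ways, with 4 of 19 members higher and 4 lower. The genes per3 (-3.12, SE 0.33), nr1d1 (-2.07, SE 0.30) and nr1d2 (-1.42, SE 0.18) fell, and npas2 rose by 2.20 (SE 0.33).

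Among enzymes of foreign compound metabolism at day 28, 12 of 42 members of the conjugation and transport list fell and 2 rose (adjusted p = 0.785 with an estimated correlation), with the glutathione transferase gsta1 at -1.32 (SE 0.27). The aryl hydrocarbon receptor targets cyp1a1 and tiparp rose by 0.93 (SE 0.25) and 0.85 (SE 0.18), each in 12 of 12 fish. In all, 3 of 5 members of that list rose and 1 fell (camera adjusted p = 0.107). In the stellate cell and fibroblast list 11 of 30 members fell, col1a2 (-1.97, SE 0.25) among them, and 5 rose (adjusted p = 0.77 with an estimated correlation). In the cell cycle list 7 of 45 members fell, ccne1 (-1.78, SE 0.25) among them, and 1 rose (adjusted p = 0.906 with an estimated correlation). Also lower were the iron exporter slc40a1 (-1.76, SE 0.29) and the steroid enzyme hsd17b12 (-2.63, SE 0.28), and cyp7a1 was higher (1.77, SE 0.65), with its call lost in 12 of 31 alternatives. The median of the hepatocyte list was 0.07 at this time. Time in the cage and calendar time went together in this comparison.

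The last question was how the sexes differed. In caged controls, 16 names were called, 14 of them lower in males, among them yolk precursors and an aspartic protease. The protease ctse-a was at 0.273 ± 0.317 CPM (SD, n = 18) in males and 52.3 ± 57.6 CPM (n = 18) in females (log2 change -7.61, SE 0.70, adjusted p = 1.02e-12), with 18 of 18 males below the female median. The names Vitellogenin (Fragment) and vtg1 were lower in males, with changes of -4.29 (SE 0.72, adjusted p = 0.000282) and -3.13 (SE 0.69, adjusted p = 0.0325), the latter call being lost in 10 of 45 alternatives. In the estrogen-responsive egg protein list 2 of 5 members were lower (camera adjusted p = 9.03e-06; adjusted p = 0.00275 with an estimated correlation), while esr1 had a change of -0.55 (SE 0.28, adjusted p = 0.426). Also lower in males were the calcium-binding rcn1 (-1.86, SE 0.30) and the kinase fam20c (-1.33, SE 0.22), each in 18 of 18 males.

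In the ribosomal protein list 2 of 88 members were lower in males, rpl23 (-0.65, SE 0.14) and rps23 (-0.61, SE 0.14), with calls lost in 20 and 25 of 45 alternatives, and 65 were lower and 3 higher when adjusted over the list alone (adjusted p = 0.195 with an estimated correlation). In the unfolded protein response list, 0 of 26 members passed over all genes and 11 were lower when adjusted over the list alone (adjusted p = 0.211 with an estimated correlation). In the lymphocyte list, 0 of 18 members passed over all genes and 10 were higher in males when adjusted over the list alone (adjusted p = 0.195 with an estimated correlation). In wild fish at day 0, 1 name was called, ctse-a, at 0.212 ± 0.202 CPM (n = 6) in males and 29.1 ± 27.8 CPM (n = 4) in females (log2 change -7.06, SE 1.24, adjusted p = 0.00357; 6 of 6 males below the female median). There, Vitellogenin (Fragment) had a change of -6.75 (SE 1.41, adjusted p = 0.0636) and vtg1 of -6.17 (SE 1.42, adjusted p = 0.155), and the egg protein list lost its camera call with an estimated correlation (adjusted p = 0.0934). The count of 16 in caged controls ran from 6, without day 7 control male M71, to 54, without day 14 control male M190. It was 120 with limma-voom and 172 with DESeq2.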

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

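All tests reported in this part were chosen after the results they concern were seen, except the test of the match score of rat and mouse names, the test for fish far from their group and the interaction tests. Chance alone puts a fish beyond the limit used here in about 1 in 20 groups.

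The first pattern is the set of names with a rat or mouse match that are higher in effluent at day 7 and in caged controls at day 14. Genes of the fish that merely resemble rodent genes are argued against, because over the 26 called names the median match score was 0.988 per base of the cluster, where 1 is an identical match over the full length and named clusters without such a match have a median of 0.302. The names moved together, as rodent RNA in the libraries would require, with medians over all 70 names of 2.13 at day 7 and 2.22 at day 14. A candidate explanation is therefore rat or mouse RNA that reached some libraries during sampling or preparation. The 2 species were not told apart. All clusters with a rat or mouse match, fish genes that resemble them included, held 0.148% to 0.459% of reads. The step at which such RNA entered stays open, and no biological explanation was tested. The signal was not shared by all fish of the raised groups and went with their label numbers. Day 7 effluent fish with the lowest numbers, M132 and F141, had means over the 70 names of 0.03 and 0.08 log2 CPM. Day 14 controls with the highest numbers, M242 and M245, had 0.08 and 0.10. The other fish of these groups had 0.38 to 1.94, except F152 (-0.69). In the remaining groups the highest mean was 0.91 (M365). Why the signal differs, between groups or along the label numbers, stays open.

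The second pattern is the fall of cholesterol synthesis genes in caged controls against day 0. Fewer hepatocytes in the sampled pieces are argued against, because the hepatocyte list had medians of -0.02, -0.12 and 0.07 on the 3 days, the lowest being -0.12. Gonad, intestine or muscle tissue in the pieces is argued against as well. At least 21 of the 27 members stayed lower on every day without the 13 libraries and with the gonad, intestine and muscle covariates. Other tissues were not tested this way. A batch of the day 0 libraries cannot be told apart from caging, because all day 0 fish form 1 group, and the share of all names called was 2.2% at day 7, 8.2% at day 14 and 25.2% at day 28. Caging, diet, season and the time since capture are open biological explanations that the design does not separate.

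The third pattern is the lower level of red blood cell genes in effluent fish. Random assignment of fish is argued against: water was permuted 100000 times within day and sex, and the difference of the list mean of -0.58 had a two-sided permutation p of 1e-05, the smallest these permutations can give, with differences from -0.79 to -0.41 in 6 of 6 combinations of day and sex. Gonad, intestine or muscle tissue in the pieces is argued against, because the list median stayed at -0.67 or lower under both added settings. Other tissues, blood-rich ones included, were not tested this way. Less blood left in the sampled pieces met its prediction: 0 of the 13 members with at least 1 CPM had a change above -0.2. The falls were unequal, from -1.14 (SE 0.23) for hbb2 to -0.44 (SE 0.17) for ank1 and -0.25 (SE 0.18) for ca2. Blood volume in the pieces may be what differed, but fewer red cells in the living fish would lower these genes too. The test therefore cannot tell these explanations apart. Fewer red cells in the living fish and effects of single raceways stay open, as untested. Each combination of day and water held its own run of label numbers. An effect of sampling or preparation order therefore cannot be told apart from water in any effluent comparison.

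The observed numbers of calls were set against permuted splits of the same fish. For caged controls against day 0, chance can be excluded on every day: 1 of 100 splits gave as many calls, with 305, 1137 and 3488 observed and at most 52, 239 and 792 in the other splits. For effluent against river water 70 splits were used. At day 14, 390 calls were observed and at most 239 came from other splits. There, 1 of 70 gave as many, the smallest share these splits can give. As this is 1 of 12 comparisons tested this way, that share does not exclude chance. The count of 390 also rests on a few fish: it was 47 without M259, 51 without M209, 114 without F227 and 0 without the 13 libraries, all below that 239. In females at day 14, 2 of 70 splits were as large. With 14 observed and 15 in another split, the observed count does not lie beyond the others, and chance is not excluded there. No allowance was made for the 12 comparisons tested this way. Nor can chance be excluded at day 7 (45 observed, at most 2104, 7 of 70 as large), at day 28 (3, at most 55, 8 of 70) or for the mean of the 3 days (8, at most 507, 8 of 70). In males it cannot be excluded at day 7 (1, at most 20, 45 of 70), day 14 (590, at most 880, 8 of 70) or day 28 (0, at most 9, 70 of 70), nor in females at day 7 (2, at most 2742, 24 of 70) or day 28 (0, at most 47, 70 of 70). The same holds for the difference between sexes (1, at most 2108, 30 of 70) and between days 28 and 7 (4, at most 411, 13 of 70). Splits that call several times the observed number at days 7 and 28, in the mean of the 3 days and in these differences point to a structure of the samples other than water. For the sexes chance cannot be excluded for the number of calls. In caged controls 16 calls were observed, with at most 715 in other splits and 7 of 100 as large. In wild fish 1 call was observed, with at most 8 in other splits and 57 of 100 as large. The 715 point to a structure of the samples other than sex. These counts do not test single names, and ctse-a stayed called in caged controls under every alternative.

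Of 377 combinations of a group with the 27 measures tested, 52 had a fish far from the others, 13.8%, in 37 fish. On the first principal component these were day 0 male M61 (52.6), day 7 effluent male M180 (130.6), day 14 control female F227 (49.7) and day 28 effluent female F395 (46.7). On the second component they were day 14 effluent female F256 (38.5) and day 7 control male M110 (37.1). The ratio uses the gap to the nearest fish, so odd fish of the same group can hide each other. Not flagged on the first component were F158 (166.7), M209 (159.1), F145 (142.9), F93 (127.3), F74 (127.1) and M223 (84.3). These fish had oocyte means of 5.00 to 6.94 log2 CPM. M259 (132.5) was not flagged on the second component. The first component held 20.6% of the variance. The gonad list mean was high in day 0 female F55 (0.62) and male M61 (1.87) and in day 14 control female F227 (1.86), whose zp3 was 10.79 and esr1 -0.84. The muscle list mean was high in day 0 female F53 (2.37), day 7 effluent male M143 (2.47), day 14 effluent female F256 (0.57), day 28 control female F343 (2.02) and day 28 effluent male M375 (1.79). The intestine list mean was high in day 7 control female F74 (4.05) and male M110 (4.96), day 14 control male M207 (3.89) and day 14 effluent female F256 (5.83). Day 14 effluent male M259 was low in the hepatocyte (6.12), red blood cell (1.30) and endothelium (1.84) lists and in cyp1a1 (4.68), cyp3a27 (7.97) and pck1 (5.82). Single list means stood apart in day 0 male M40 (neutrophil, 1.97), day 14 effluent females F272 (exocrine pancreas, 5.23) and F289 (macrophage, 2.30), day 28 control female F317 (red blood cell, 3.76) and day 28 control male M308 (lymphocyte, 3.86).

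Among indicator genes, in log2 CPM, Vitellogenin (Fragment) was low in day 0 female F53 (0.55) and high in day 14 control female F216 (8.97) and day 28 effluent female F363 (5.33), and vtg1 was high in day 14 control male M207 (9.41). The gene cyp3a27 was low in day 0 female F55 (8.72) and high in day 14 control female F191 (11.5), and cyp1a1 was low in day 14 control male M209 (7.69). The gene cyp7a1 was high in day 7 control female F96 (6.02). Metallothionein-like protein type 3, near the floor in most fish, was high in day 7 control male M71 (-0.42), day 14 control male M190 (0.87), day 14 effluent male M255 (-0.31), day 28 effluent female F367 (-1.48) and day 28 effluent male M401 (-0.20). The chaperone hsp70 was high in day 7 control male M117 (4.71) and day 14 effluent female F254 (4.12) and low in day 7 effluent female F152 (1.48). The gene pck1 was low in day 7 control female F93 (7.74) and day 7 effluent female F158 (7.05), and igf1 in day 7 control male M64 (3.07). Serum amyloid A-5 protein was low in day 7 control female F112 (-1.11) and high in day 7 effluent male M132 (6.60).

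Interaction tests passed for 5 names, and by the permuted splits above chance cannot be excluded for these counts. Between sexes the effluent effect of ddb_g0292642 had a difference of 9.84. Between day 28 and day 7 the differences were -2.26 for art3, 4.69 for mb, 9.26 for myl7 and -4.33 for napsa. Without the 13 libraries the differences were 9.83, -2.11, 3.84, 8.13 and -4.44 in the same order, with adjusted p from 0.125 to 0.335, so the calls were lost while most differences stayed near their size.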

How the results depend on the processing

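All alternatives named as added below were chosen after seeing the data, and every other one was planned before. The fall of cyp51 in caged controls stayed called under every alternative run, from -4.08 to -3.62 at day 7 and -5.17 to -4.73 at day 14, as did the rise of hsp70 at day 28 (2.77 to 4.00) and the sex difference of ctse-a in caged controls (-8.06 to -7.31). The fall of slc4a1 in the mean effluent comparison kept its direction (-1.17 to -0.33) and lost its call with limma-voom (adjusted p = 0.16), with the pancreas and red blood cell covariates, of which the second holds slc4a1 itself, and without the 13 libraries (adjusted p = 0.0518). Where a cause is not named, the cause was not tested. DESeq2 size factors moved no total count by more than 1.5 times, though the names higher in males in caged controls went from 2 to 4, and no median of all names by more than 0.029 on the log2 scale.

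In this paragraph the order is effluent against control at day 7, 14 and 28, males at day 7, 14 and 28, females at day 7, 14 and 28, the mean of the 3 days, the difference between sexes, the difference between days, caged controls at day 7, 14 and 28, sexes at day 0 and sexes in caged controls. DESeq2 called 84, 607, 53, 291, 955, 29, 17, 52, 51, 32, 13, 47, 531, 1493, 3770, 21 and 172 names. Limma-voom called 0, 0, 0, 2, 0, 0, 0, 0, 1, 0, 0, 1, 819, 2469, 4712, 0 and 120. A fit of the compared groups alone called 1, 1, 0, 0, 0, 0, 0, 0, 0, 7, 0, 1, 449, 1492, 3747, 0 and 18, from fewer fish behind each spread. Testing each cluster on its own called 190, 807, 26, 22, 451, 3, 23, 4, 3, 8, 0, 42, 522, 2268, 9558, 4 and 65. The pancreas and red blood cell covariates gave 19, 84, 6, 0, 611, 2, 5, 12, 1, 0, 2, 2, 368, 1277, 3184, 1 and 69. Without the 13 libraries (added) there were 11, 0, 1, 3, 2, 0, 1, 26, 1, 0, 0, 0, 241, 1173, 3916, 1 and 113. The gonad, intestine and muscle covariates (added) gave 41, 0, 6, 2, 5, 3, 8, 2, 12, 3, 0 and 7 in the first 12 and 820, 4061, 18 and 68 in the last 4, with 119 names higher in caged controls at day 7. Without clusters matching rat or mouse (added) day 14 had 161 higher names, and the numbers called in the other comparisons were 11, 4, 1, 557, 0, 1, 14, 0, 8, 1, 2, 296, 1086, 3488, 1 and 18. Sex as an additive term gave 0, 3 and 0 in the first 3. Without the filter the difference between sexes gave 0. Leaving out each fish in turn gave, from lowest to highest, 22 to 50, 47 to 489, 0 to 6, 0 to 22, 1 to 846, 0 to 5, 0 to 6, 2 to 20, 0 to 5, 1 to 11, 0 to 5, 1 to 7, 185 to 376, 749 to 1315, 3070 to 3809, 1 to 4 and 6 to 54.

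Some directions turned. In the mean effluent comparison, hbaa1, ba2 and vtg1 went to 0.00, 0.06 and 0.16 with the pancreas and red blood cell covariates, of which the second is built from hbaa1 and its companions. Parvalbumin beta in females at day 14 went to 4.92 with the muscle covariate, which is built from it. Leaving out single fish took the uncalled change of esr1 from -0.06 to 0.11 and that of cyp3a27 from -0.05 to 0.11. It was negative for esr1 without day 7 effluent female F141 (-0.06) or male M132 (-0.01) and for cyp3a27 without effluent female F164. The uncalled list of conjugating enzymes and transporters at day 7 turned its direction without control female F69, effluent female F158 or effluent male M180 (adjusted p = 0.796, 0.342 and 0.827), and its adjusted p ran from 0.278 to 0.925 over all fish left out. Of 154 called results for single genes, where a gene counts once in each comparison, 96 stayed called with limma-voom and 58 did not. All 154 stayed called with DESeq2 size factors. Depth limits names below about 1 CPM.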

Other observations

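Oocyte transcripts appeared in livers of both sexes. Of the 82 libraries, 12 had a mean of the 4 oocyte genes gdf9, bmp15, zar1 and zp2 above 2 log2 CPM, 4 of them from males (M61, M180, M209 and M223) and 8 from females (F74, F93, F100, F145, F152, F158, F227 and F395). The means ran from 3.69 to 6.74 in these males and from 2.93 to 6.94 in these females. The protease ctse-a was at -2.74, 0.79, -1.20 and -1.31 log2 CPM in males M61, M180, M209 and M223, where females had a median of 5.08 and a lowest value of -2.74. The other males had at most 0.13, so this gene was within the male range in M61, M209 and M223 and above it in M180. With a female as low as -2.74, 1 gene cannot settle the recorded sex. A wrongly recorded sex would not by itself bring oocyte transcripts, since most females lacked them. The libraries outside the 12 had a median oocyte mean of -1.88. Whether other tissue was in these pieces, and whether any sex was recorded wrongly, stay open.

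Further genes changed in caged controls at day 28. In the amino acid breakdown list 8 of 45 members fell and 2 rose (camera adjusted p = 0.41), among them amt, of the glycine cleavage system (-1.37, SE 0.21) and kmo, of tryptophan breakdown (-1.09, SE 0.22). In the metal handling list 2 of 13 members rose, slc11a2, an iron importer, among them (1.0, SE 0.15) (camera adjusted p = 0.392). In the bile acid list 3 of 15 members fell, slc27a2 (-1.30, SE 0.20) among them, and 1 rose (camera adjusted p = 0.107). The lipid regulator srebf1 rose by 0.92 (SE 0.23), in 12 of 12 fish, and the growth hormone receptor ghr fell by 0.79 (SE 0.21).

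Clusters with a rat or mouse match number 3962, of which 2845 are named, and hold a median of 0.256% of the reads of a library. Group medians ran from 0.184% in day 0 males to 0.296% in day 28 control females.

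The authors' deposited table gives q-values below 0.05 for 280 clusters at day 7 in effluent against river water (25 of them lower), 462 at day 14 (283 of them lower) and 32 at day 28 (20 higher, 12 lower). Against day 0, the authors' deposited table has 724 clusters for river water at day 7 and 3014 at day 14 (1680 higher, 1334 lower). For effluent against day 0, the authors' deposited table has 1334 clusters at day 7, 2638 at day 14 and 6887 at day 28.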
